A study of Mus musculus with 26 samples.

How the data were processed

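RNA-seq, ATAC-seq and Hi-C were done on mouse frontal cortex, per the labels. The RNA was total RNA from 7 HET and 7 WT mice, selected for poly-A, made into libraries with random primers and sequenced as paired reads of 150 bases on an Illumina NovaSeq, per the labels' protocols. The authors' deposited RNA values are raw counts per gene, with 1 table per library. Per the file headers, featureCounts 2.0.1 counted reads over exons summed by gene ID against the Ensembl GRCm38 annotation, release 102, with strand ignored (setting 0). The command in the header has no option to count read pairs as fragments, so each mate can count by itself, and reads that map to several places or overlap several genes were left out by default. STAR, Trimmomatic, Subread and DESeq2 were named without versions, and the build as GRCm38.p6, per the submitters' processing notes. The design text of the series speaks of 13383 expressed genes; its filter is not given in the sources used here, and 18050 genes were tested here.

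The ATAC-seq values are 2 deposited peak lists with chromosome, start and end of each peak on mm10 (the same assembly as GRCm38), 1 list per genotype. The names of the deposited lists point to libraries merged within a genotype, and which libraries were merged is not given in the sources used here. The lists carry no height, fold or q value. Bowtie2 2.4.4, SAMtools 1.9, bcl2fastq 2.20, MACS3, deepTools, edgeR and featureCounts were named for the ATAC-seq samples, per the submitters' processing notes, and caller settings and depth are not given in the sources used here. Of the 8 ATAC-seq samples, 3 were labelled HET, 3 WT, 1 PAT and 1 Control. Hi-C samples (2 HET, 2 WT, for which HiC-Pro 3.1.0 was named per the submitters' processing notes) were not analysed here, nor were the PAT and Control samples.

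Each count table held 55487 genes, of which 55141 IDs matched a symbol. Library totals ran from 32814841 to 48291175 counts. A chi-square comparison of counts over genes for all 91 library pairs gave at least 9.83 per degree of freedom (WT 5 and WT 6), so no library looked like a second copy of another. Genes were kept by edgeR's filterByExpr with genotype as the group, which left 18050. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, robust, genotype as the single term, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.248. CPM values in the text are TMM-scaled, and errors are SD over 7 libraries. This test, the samples in it, the naming rule, 40 gene lists and most alternatives were chosen before the data were examined. The Adnp level was also compared by an exact permutation test over 3432 splits.

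The lists covered Adnp and its paralog, ChAHP partners, BAF subunits, clustered protocadherins, Wnt ligands and receptors, beta-catenin components, Wnt targets, Wnt antagonists, microtubule and actin genes, autism risk genes, excitatory, inhibitory and presynaptic genes and immediate early genes. They also covered markers of 15 cell types, brain regions and blood, and interferon, complement, glucocorticoid, heat shock, oxidative phosphorylation, mitochondrial, ribosomal, autophagy, imprinted and sex-linked genes. Of the 40 lists, 38 with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the correlation within each list estimated, and 2 were described only. Camera with a preset correlation of 0.01 and fry, a rotation test that asks whether a list moves on balance to one side, were alternatives. An exact permutation test of each list mean was added after the data were examined. The result of 1 gene, and the counts of called genes in the 2 lists that hold it, are not reported here.

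Named genes were Adnp, Adnp2 and the sex-linked genes, then the 10 largest rises and 10 largest falls among genes at adjusted p under 0.05 with a mean log2 CPM of at least 0 (predicted genes and pseudogenes left out). To these came up to 4 called members of each list with the smallest p, and the member of each cell type or region list with the highest WT level. For peaks they were those at Adnp, the promoter peaks of genes named by size, and the 5 strongest promoter peaks of each genotype. The strength was to be the caller's fold value; as the lists have none, peak width was used in its place.

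Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter of 1 CPM in 7 libraries, the replicate number as a block, limma-voom with sample weights, Y-linked expression or 1 surrogate variable (sva 3.50.0) as a covariate, an adjusted p under 0.1, and each library left out. Chosen after seeing the data were marker means as covariates (excitatory alone, or excitatory, striatal and thalamic together), fits without the 2 libraries lowest in excitatory markers or without 5 libraries at the ends of the first principal component, the widest HET peaks in equal number, peaks of at least 300 bp, the promoter test with marker covariates or centred by expression, and the beta-catenin list mean without its 2 members that also stand in the thalamic list.

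Peak overlap was computed with bedtools 2.31.1 at a minimum of 1 bp, with exact binomial 95% intervals, which cover counting error only. Promoters were taken as 1 kb either side of the gene's start in the count tables' annotation, and other peaks were placed in exons, introns or intergenic sequence. The median RNA fold change was compared between promoter classes with 100000 resamples. Coordinates are 1-based on GRCm38. Tools were R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

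The gene test was checked on counts simulated for HET against WT with 200 genes changed, over 17768 genes. It recovered 5 of 50 genes changed 1.25-fold, 26 of 50 changed 1.5-fold, 29 of 50 changed 2-fold and 44 of 50 changed 4-fold, and called 3 of 17545 unchanged genes. A simulated list of 30 genes raised 1.5-fold was called by camera and an untouched list was not. Counts were drawn for each gene separately, so the simulated genes had no correlation and no shared tissue difference. In the real lists camera estimated correlations such as 0.438 for immediate early genes and 0.944 for oligodendrocyte markers. Power and error for genes that move together were thus not checked. For the promoter comparison, a simulated shift of 0.2 in 500 genes gave a permutation p of 0.0005, the smallest its 2000 resamples can give, and no shift gave 0.89.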

Results

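Adnp encodes activity-dependent neuroprotective protein, a zinc-finger homeodomain protein that works in chromatin complexes, and mutations in its human counterpart cause a neurodevelopmental syndrome with autism. The series held 26 samples of mouse frontal cortex, from adolescent animals where an age was stated. Apart from 1 ATAC-seq sample labelled PAT and 1 labelled Control, the animals carried an Adnp frameshift on a single allele (HET) or the wild-type gene (WT). RNA sequencing covered 7 HET and 7 WT libraries. Open chromatin (ATAC-seq, which reads where a transposase can enter the genome) was given as 1 peak list for HET and 1 for WT, from a group of 8 ATAC-seq samples. The 4 chromosome conformation (Hi-C) samples and the ATAC-seq samples labelled PAT and Control were not analysed here. Library totals ran from 33280785 to 47079906 counts in HET and from 32814841 to 48291175 in WT. The 50 most abundant genes took 12.27% to 13.08% of the counts of a library, and mitochondrial genes 4.39% to 5.64%. Per the labels' protocols the RNA came from 7 mice per genotype, so the p-values below measure the spread between mice as far as the labels say.

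The first question was whether the mutated gene itself differed in mRNA level. Adnp (ENSMUSG00000051149, GRCm38 chromosome 2, 168180986 to 168207112, minus strand) stood at 6.90 ± 1.30 CPM (counts scaled to library size) in HET and 6.55 ± 0.87 CPM in WT (SD, n = 7 each). The log2 fold change was 0.07 (SE 0.13), with a 95% confidence interval from -0.20 to 0.35 and an adjusted p of 0.772 in edgeR's quasi-likelihood test. A two-sided exact permutation test of log2 CPM over the 3432 splits of the 14 libraries gave p = 0.615. A lower level was not detected. A frameshift need not lower the mRNA, so this level does not check the genotype labels. The paralog Adnp2 stood at 27.9 ± 2.23 CPM in HET and 31.4 ± 2.79 CPM in WT, with a log2 fold change of -0.17 and an adjusted p of 0.162 (edgeR). The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were expressed in all 14 libraries, with Ddx3y between 59.1 and 91.8 CPM, and the X-inactivation transcript Xist was too low to be tested. Mean Ddx3y was 76.6 ± 7.94 CPM in HET and 67.2 ± 6.46 CPM in WT, Kdm5d 29.2 and 26.4 CPM, Eif2s3y 40.0 and 39.7 CPM, and Uty 15.2 and 15.1 CPM. No sex-linked member or Adnp gene changed in edgeR with all libraries, and DESeq2 and limma-voom called 0 of them as well. Without WT 4 edgeR called Ddx3y higher (log2 fold change 0.23, adjusted p 0.0475). At unadjusted p under 0.05 there were 2 sex-linked genes and 1 of the Adnp pair. Adjusted over the list alone, Adnp2 fell and no sex-linked gene passed.

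The main comparison asked which genes differed between HET and WT frontal cortex. Several genes with low levels in WT cortex rose severalfold, with every HET library above the highest WT library. Sycp2, which encodes a component of the synaptonemal complex of meiotic chromosomes (chromosome 2, 178345293 to 178407685), rose from 1.35 ± 0.34 to 5.48 ± 0.68 CPM (4.05-fold, adjusted p 3.3e-05 in edgeR). The serine protease gene Prss41 (chromosome 17, 23836785 to 23844172) rose 11.01-fold, from 0.182 ± 0.0870 to 2.03 ± 0.523 CPM (adjusted p 6.2e-05 in edgeR), and its family member Prss50 (chromosome 9, 110857967 to 110864629) rose 5.10-fold, from 0.712 ± 0.314 to 3.64 ± 0.47 CPM. Rnf17, a Tudor-domain protein of germ cells (chromosome 14, 56402581 to 56525032), rose 4.15-fold from 0.672 ± 0.248 to 2.79 ± 0.622 CPM. Best1, a calcium-activated chloride channel (chromosome 19, 9985174 to 10001633), rose 4.30-fold from 1.32 ± 0.527 to 5.70 ± 1.55 CPM. Ighm, the heavy chain gene of immunoglobulin M (chromosome 12, 113418558 to 113422730), fell 2.70-fold from 25.03 ± 7.32 to 9.28 ± 2.50 CPM, and each HET library lay below the lowest WT library.

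Across 18050 tested genes, 175 changed at an adjusted p under 0.05 in edgeR's two-sided quasi-likelihood test, of which 106 rose and 69 fell in HET. At unadjusted p under 0.05 there were 4007 genes. Among the called genes 52 were higher in all 7 HET libraries than in any WT library and 20 were lower. The count shifted when a single library was left out. It became 11 without HET replicate 1, 13 without HET 2, 109 without HET 3, 19 without HET 4, 241 without HET 5, 1110 without HET 6 and 11 without HET 7, and it was 13 without WT 1, 29 without WT 2, 20 without WT 3, 1672 without WT 4, 15 without WT 5, 12 without WT 6 and 41 without WT 7. Called with every library left out in turn were 11 genes, 10 that rose and 1 that fell: Sycp2, Prss41, Prss50, Rnf17, Best1, Card10 and Ighm, and, outside the naming rule and chosen after their values were seen, E230025N22Rik, Gm15707, Plcg2 and Sec24d. The Ighm call still ended with a replicate block (adjusted p 0.0610), Y-linked expression (0.441), 1 surrogate variable (0.0671), the excitatory marker mean (0.0774) or 3 tissue marker means (0.0551) in the edgeR fit, and without the 2 libraries lowest in excitatory markers (0.0734) or the 5 at the ends of the first principal component (0.322), with log2 fold changes from -1.42 to -0.94. Prss50, Best1 and Card10 lost theirs with the Y-linked covariate (adjusted p 0.266, 0.321 and 0.540), Best1 and Card10 without those 5 libraries (0.135 and 0.322) and Card10 with the block (0.0610). The Y-linked genes behind this covariate averaged 5.085 ± 0.050 log2 CPM in HET and 5.003 ± 0.070 in WT (two-sided exact permutation p = 0.0309, 0.117 after adjustment over 40 lists). The covariate itself was the log2 of their summed CPM without TMM scaling, and its own overlap with genotype was not measured. As these genes lay higher in HET, the covariate stands in for genotype at least in part. A call lost with it, here or below, cannot be told apart from that overlap. DESeq2 called 1403 genes and limma-voom with sample weights 1886, and all 175 edgeR calls were among each. With the mean of the excitatory neuron markers as a covariate 13 genes changed, 12 of them shared with the 175, and with excitatory, striatal and thalamic marker means as covariates 27 changed, 21 of them shared.

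**Figure D1:**
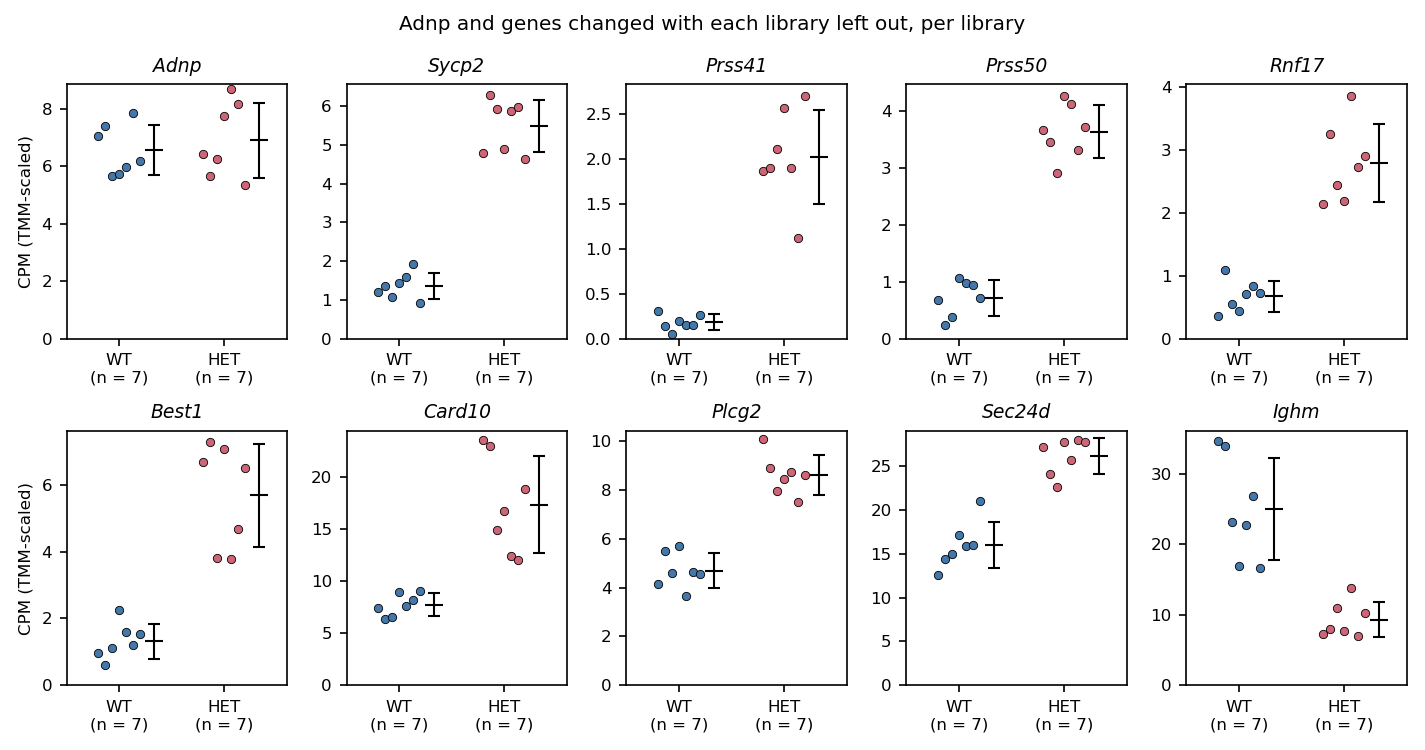
Expression in CPM (TMM-scaled, linear axis from 0) of Adnp and 9 of the 11 genes called with each library left out, 1 point per library, blue for WT and red for HET, with the mean and SD beside the points (n = 7 each). Adnp overlapped between genotypes, while all 7 HET libraries lay above the highest WT library for Sycp2, Prss41, Prss50, Rnf17, Best1, Card10, Plcg2 and Sec24d, and below the lowest for Ighm.

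**Figure D2:**
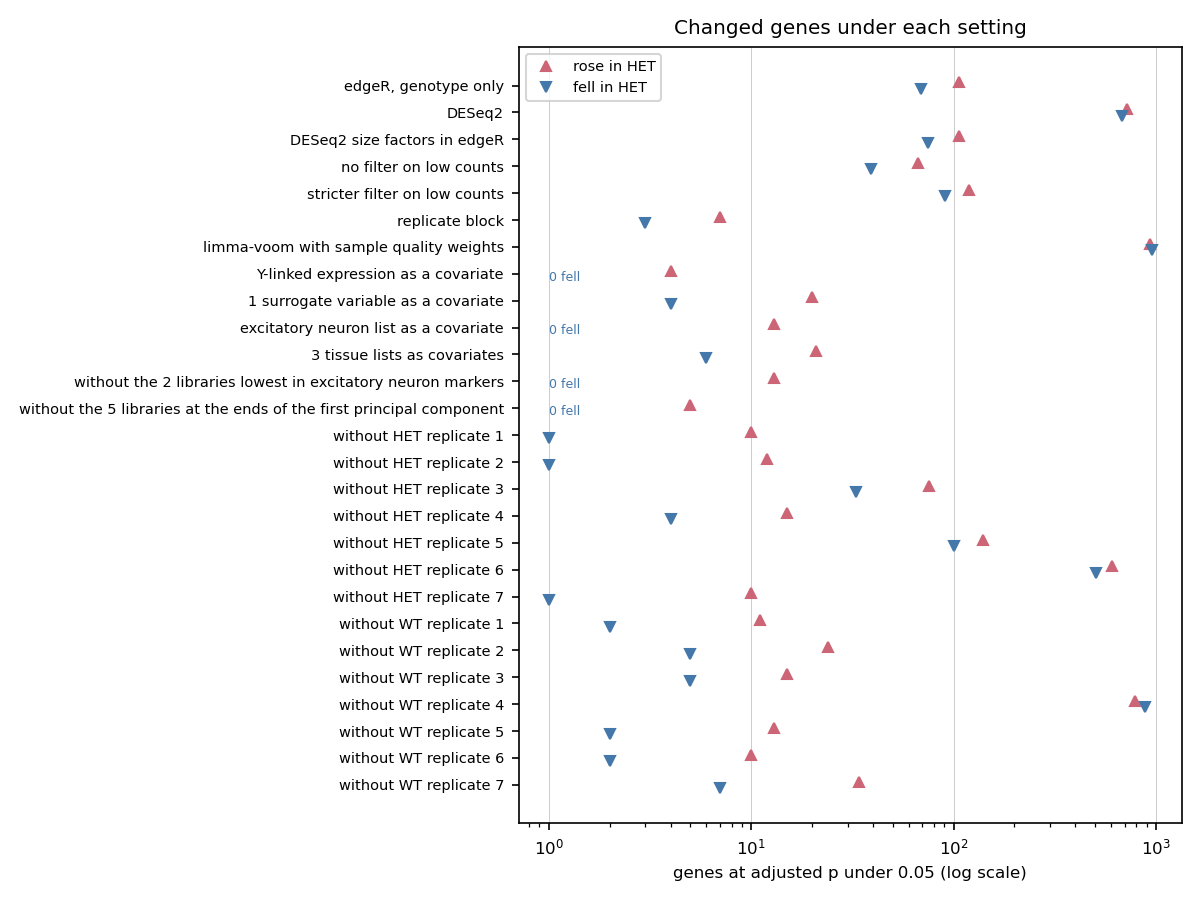
Number of genes at adjusted p under 0.05 (log axis) that rose in HET (red, pointing up) or fell (blue, pointing down) under each setting; a count of 0 is written as text. The genotype-only edgeR test gave 106 and 69, DESeq2 722 and 681, and the test without HET replicate 1 gave 10 and 1.

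Other genes named by size covered receptors, signalling proteins and noncoding RNAs. Rec8, the meiotic cohesin subunit, rose from 5.58 ± 3.47 to 19.02 ± 3.71 CPM (log2 fold change 1.76, adjusted p 0.0332 in edgeR), and WT replicate 4 alone among the WT libraries stood at 12.6 CPM. Xlr3a rose from 0.799 ± 0.420 to 4.22 ± 2.24 CPM (2.395, adjusted p 0.0306), with 6 of 7 HET libraries above the highest WT; it has near-identical X-linked copies that can share its reads, so its level is uncertain. Gabrr2, a rho subunit of the GABA-A receptor, rose from 0.524 ± 0.201 to 1.76 ± 0.799 CPM. Card10, a scaffold of NF-kB signalling, rose from 7.74 ± 1.09 to 17.4 ± 4.70 CPM (1.17, adjusted p 0.00379). Abhd11os rose by 1.12 on the log2 scale (adjusted p 0.0499); it is an antisense transcript and the counting ignored strand, so reads of its partner gene cannot be told apart from its own. Among the genes that fell, the slow troponin gene Tnnc1 went from 9.30 ± 4.84 to 2.69 ± 0.401 CPM (-1.79, adjusted p 0.0375) and the Wnt ligand gene Wnt10a from 11.9 ± 5.87 to 3.58 ± 1.46 CPM (-1.73, adjusted p 0.0482). Eya4, a transcriptional coactivator with phosphatase activity, had a log2 fold change of -1.07 (adjusted p 0.0197), and the immune checkpoint receptor gene Lag3 one of -0.95 (adjusted p 0.0197), with all 7 HET libraries below the lowest WT library for both. Further falls were those of the noncoding RNAs Panct2 (-1.15) and Pantr1 (-0.99), the hyaluronan receptor gene Layn (-0.997), the ERK phosphatase gene Dusp6 (-0.91, 81.2 to 43.3 CPM) and Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1 (-0.89).

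Apart from the 7 rule-named genes called with every library left out, the calls of single genes ended in at least some of those fits. With 175 genes at an adjusted p under 0.05 and 1195 under 0.1, many calls lay near the threshold. These losses therefore need not come from particular mice. Eya4 and Lag3 were called in 9 of the 14 fits that left out a library, and both had a highest adjusted p of 0.0616 in edgeR. Without HET 1, HET 2, HET 7 or WT 5 both calls ended, as did that of Eya4 without WT 1 and that of Lag3 without WT 6. Rec8, Gabrr2, Xlr3a, Abhd11os, Tnnc1, Wnt10a, Panct2, Pantr1, Layn, Dusp6 and Ppp1r3g were called in 2 to 5 of those fits, with the highest adjusted p between 0.0818 and 0.115. All 11 lost their call without HET 1, 2, 4 or 7 and without WT 1, 2, 3, 5 or 6, and all but Xlr3a and Tnnc1 without WT 7. Without HET 3 the calls of Abhd11os, Wnt10a, Panct2, Layn and Dusp6 ended too, and without HET 5 those of Abhd11os and Dusp6. The direction held in all 14 fits for each gene, with log2 fold changes from -1.97 to -1.59 for Tnnc1 and from 1.64 to 2.11 for Rec8. With Y-linked expression as a covariate the calls of all 13 ended in edgeR (adjusted p from 0.522 to 0.9997), with log2 fold changes of -0.29 for Tnnc1, -0.39 for Wnt10a, -0.36 for Layn, -0.497 for Panct2 and -0.46 for Ppp1r3g, and they ended with a replicate block as well (0.0610 to 0.0992). The Y-linked covariate stands in for genotype at least in part, as given above, so losses with it alone do not mark a gene as weak. With 1 surrogate variable Rec8 and Eya4 alone kept their calls, and Tnnc1 stood at -0.98 and Wnt10a at -0.66. With the 3 tissue marker means Rec8, Xlr3a, Eya4 and Lag3 kept theirs (adjusted p 0.00405 to 0.0457), while the others ended (0.0814 to 0.251), with log2 fold changes of -1.33 for Tnnc1, -0.93 for Wnt10a, -0.75 for Panct2, -0.66 for Pantr1, -0.69 for Layn and -0.53 for both Dusp6 and Ppp1r3g. With the excitatory mean alone none of the 13 was called (adjusted p from 0.0774).

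Because ADNP binds CHD4 and HP1 in the ChAHP complex and also interacts with BAF remodellers, chromatin lists were examined next. The 15 tested ChAHP and heterochromatin partners had a median log2 fold change of -0.01, with 7 positive and 8 negative. Of 23 BAF subunits 0 changed in edgeR, with 4 at unadjusted p under 0.05, and 1 rose adjusted over the list alone. DESeq2 and limma-voom each called 1 BAF subunit higher and 1 lower. Among 54 tested clustered protocadherins, the cell-surface proteins whose promoter choice depends on chromatin looping, 3 rose and 51 did not pass. These were Pcdhb14 (9.43 ± 0.630 to 13.3 ± 1.54 CPM, log2 fold change 0.50, adjusted p 0.0222), Pcdhgb6 (0.49, adjusted p 0.0476) and Pcdhga2 (0.59, adjusted p 0.0476). With p adjusted over the list alone, 8 protocadherins rose and 3 fell, DESeq2 called 7 higher and 3 lower and limma-voom 9 and 3, and 17 had an unadjusted p under 0.05. The gamma genes share their last exons and the cluster members resemble each other, so the split of reads between members is uncertain. Camera with an estimated correlation gave unadjusted p = 0.873 for the ChAHP list, 0.440 for BAF and 0.698 for protocadherins. The calls of Pcdhgb6 and Pcdhga2 held in 2 and 3 of the 14 fits with a library left out and that of Pcdhb14 in 9, with highest adjusted p from 0.0687 to 0.112 in edgeR. All 3 ended without HET 1, 2 or 7 or without WT 1 or 6, and both gamma genes also without HET 3 or 5 or without WT 2, 3, 5 or 7. Pcdhgb6 lost its call without HET 4 as well. The Y-linked covariate and the replicate block ended all 3 calls with log2 fold changes of 0.51 and 0.49 for Pcdhb14, 0.40 and 0.49 for Pcdhgb6 and 0.69 and 0.57 for Pcdhga2, and the 3 tissue marker means ended that of Pcdhgb6 (0.43, adjusted p 0.0984). The protocadherin median was 0.05, 0.14 with the 3 tissue marker means and 0.17 with the excitatory mean. With the excitatory mean as a covariate the unadjusted fry p for protocadherins went from 0.373 to 0.00825, and the unadjusted camera p from 0.698 to 0.0711.

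The title of the series names Wnt signalling and the cytoskeleton. Of 41 tested Wnt ligands and receptors 1 fell, Wnt10a, whose call ended in most fits with a library left out as given above, and 40 did not pass. The count was 2 risen and 1 fallen adjusted over the list alone, 3 and 1 in DESeq2 and 4 and 1 in limma-voom, with 8 at unadjusted p under 0.05. Of 34 components of the beta-catenin pathway, Tnks rose, a tankyrase that targets Axin for degradation, from 119.5 ± 6.17 to 145.0 ± 9.90 CPM (log2 fold change 0.28, adjusted p 0.0352 in edgeR), and 33 did not pass. The Tnks call held in 5 of the 14 fits with a library left out, ending without HET 1, 2, 4 or 7 or without WT 1, 2, 3, 5 or 6, where the highest adjusted p was 0.0875, and it also ended with the block, the Y-linked covariate or the 3 tissue marker means (0.21, adjusted p 0.107). The count was 1 risen and 0 fallen component adjusted over the list alone, 2 and 0 in DESeq2 and 2 and 2 in limma-voom, with 11 at unadjusted p under 0.05. The median log2 fold change of these components was 0.04, with 20 positive and 14 negative, and their mean log2 CPM was 5.93 ± 0.06 in HET and 5.83 ± 0.02 in WT. This difference of 0.10 had a two-sided exact permutation p of 0.00233 (0.0466 after Benjamini-Hochberg adjustment over 40 lists, a test chosen after the data were examined), while camera gave p = 0.666. The list holds Tcf7l2 (log2 fold change 2.30, SE 0.81, adjusted p 0.126) and Lef1 (1.248, SE 0.51, adjusted p 0.175), which also stand in the thalamic list and were picked for mention after their values were seen. Without these 2 genes the difference was 0.019 (exact permutation p = 0.457), so the list mean rested on them. Of 29 Wnt target and feedback genes 0 changed in edgeR (9 at unadjusted p under 0.05), against 3 higher and 3 lower in DESeq2, 3 and 2 in limma-voom, and 3 and 3 adjusted over the list alone. Of 15 secreted Wnt antagonists 0 changed (3 at unadjusted p under 0.05) and 0 adjusted over the list alone, and DESeq2 called 1 lower and limma-voom 1 higher and 1 lower. Camera with an estimated correlation gave p = 0.934 for ligands and receptors, 0.879 for targets and 0.855 for antagonists.

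Of 61 microtubule genes 0 changed in edgeR, with 14 at unadjusted p under 0.05, and 3 fell adjusted over the list alone; DESeq2 called 5 lower, and limma-voom 8 lower and 1 higher. Of 58 tested actin genes 1 fell, Arpc3, a subunit of the actin-nucleating Arp2/3 complex, from 96.38 ± 11 to 72.6 ± 8.55 CPM (log2 fold change -0.41, adjusted p 0.0461 in edgeR), and 57 did not pass. Its call held in 3 of the 14 fits with a library left out, those without HET 5, HET 6 or WT 4, and the highest adjusted p was 0.106. The block, the Y-linked covariate and the 3 tissue marker means (-0.23, adjusted p 0.134) ended it too. Adjusted over the list alone, 1 actin gene rose and 3 fell, DESeq2 called 1 higher and 6 lower and limma-voom 4 and 16, and 24 had an unadjusted p under 0.05. The actin median was -0.14, and -0.02 with the 3 tissue marker means. Camera with a preset correlation called both lists lower (adjusted p 0.0325 for microtubule and 0.000723 for actin genes), and neither held with an estimated correlation (adjusted p = 0.888 and 0.677). The two-sided exact permutation p of the list mean was 0.0758 for microtubule and 0.0350 for actin genes (0.233 and 0.117 after adjustment over 40 lists). The 53 tested autism risk genes had a median log2 fold change of 0.00, with 27 positive and 26 negative, and camera gave unadjusted p = 0.948 for the list.

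Lists for synapses, neuronal activity and cell types asked which parts of the cortex the differences followed. Markers of cortical excitatory neurons averaged 5.82 ± 0.84 log2 CPM in HET and 6.62 ± 0.44 in WT (difference -0.80, two-sided exact permutation p = 0.0315, 0.117 after adjustment over 40 lists). The lowest libraries were HET 4 at 4.19 and HET 1 at 5.17, and WT 4 stood at 5.73. Markers of thalamus and hypothalamus averaged 3.83 ± 1.49 log2 CPM in HET and 2.51 ± 1.603 in WT (exact permutation p = 0.142, 0.341 after adjustment). HET 4 was highest at 6.34 and HET 1 next at 5.32, while WT 1 to 3 lay between 0.74 and 1.01. WT 7 (4.42), WT 4 (4.00) and WT 6 (3.59) lay above the remaining HET libraries, which ran from 1.96 to 3.45. Camk2a, the most abundant excitatory marker, stood at 1924 ± 867 CPM in HET and 3183 ± 869 CPM in WT (log2 fold change -0.73, adjusted p 0.164 in edgeR and 0.0347 in limma-voom), and Slc17a6, the vesicular glutamate transporter of subcortical neurons, at 188.0 ± 143.5 and 65.9 ± 44.2 CPM (1.51, adjusted p 0.129). The first principal component held 39.1% of the variance and set HET 4 and HET 1 at one end and WT 1, WT 3 and WT 2 at the other. Without those 5 libraries 5 genes changed, and without HET 4 and HET 1 alone 13 changed.

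Immediate early genes, which neurons switch on with activity, all lay lower in HET. All 24 tested members had negative log2 fold changes, with a median of -0.86, although 0 passed over all genes in edgeR. At unadjusted p under 0.05 there were 16, DESeq2 called 14 lower and limma-voom 15, and 15 fell adjusted over the list alone. The list mean was 4.95 ± 0.54 log2 CPM in HET and 5.88 ± 0.37 in WT (two-sided exact permutation p = 0.00117, 0.0466 after adjustment over 40 lists). Fosb stood at 18.1 ± 6.17 CPM in HET and 40.6 ± 14.5 CPM in WT, Egr1 at 227.3 ± 99.3 and 523.5 ± 165.3 CPM, and Arc at 93.4 ± 57.7 and 321.0 ± 173.2 CPM, 3 examples chosen after their values were seen. Camera with an estimated correlation gave p = 0.0366 (adjusted p = 0.677), a preset correlation called the list lower (adjusted p 6.98e-11), and fry called it lower (adjusted p 0.0474). HET 1 and HET 4, lowest in excitatory markers, were also lowest for this list (3.98 and 4.42 log2 CPM). Among the WT libraries WT 1, highest in excitatory markers, was lowest for it (5.41). With the excitatory marker mean as a covariate the median log2 fold change was -0.55 and the unadjusted fry p went from 0.00250 to 0.0227. The median was -0.48 with the 3 tissue marker means.

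Imprinted genes, expressed from a single parental copy, lay mostly higher in HET. Of 28 tested members 24 had positive log2 fold changes, with a median of 0.42, and 0 passed over all genes in edgeR. There were 15 at unadjusted p under 0.05, DESeq2 and limma-voom each called 7 higher, and 8 rose adjusted over the list alone. Examples chosen after their values were seen were Peg3 (708.2 ± 210.9 CPM in HET and 451.1 ± 117.0 CPM in WT), Ndn (293.8 ± 89.4 and 184.5 ± 57.2 CPM) and Meg3 (2800 ± 402 and 2201 ± 350 CPM). The list mean was 6.26 ± 0.25 log2 CPM in HET and 5.72 ± 0.43 in WT (exact permutation p = 0.0187, 0.117 after adjustment over 40 lists). Camera with an estimated correlation gave p = 0.0424 (adjusted p = 0.677), a preset correlation called the list higher (adjusted p 7.81e-06), and fry called it higher (adjusted p 0.0474). With the excitatory marker mean as a covariate the median was 0.23 and the unadjusted fry p went from 0.00221 to 0.0543, over 0.05. The highest list means were those of HET 1 (6.65), HET 4 (6.58) and WT 4 (6.34), the libraries lowest in excitatory markers.

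**Figure D3:**
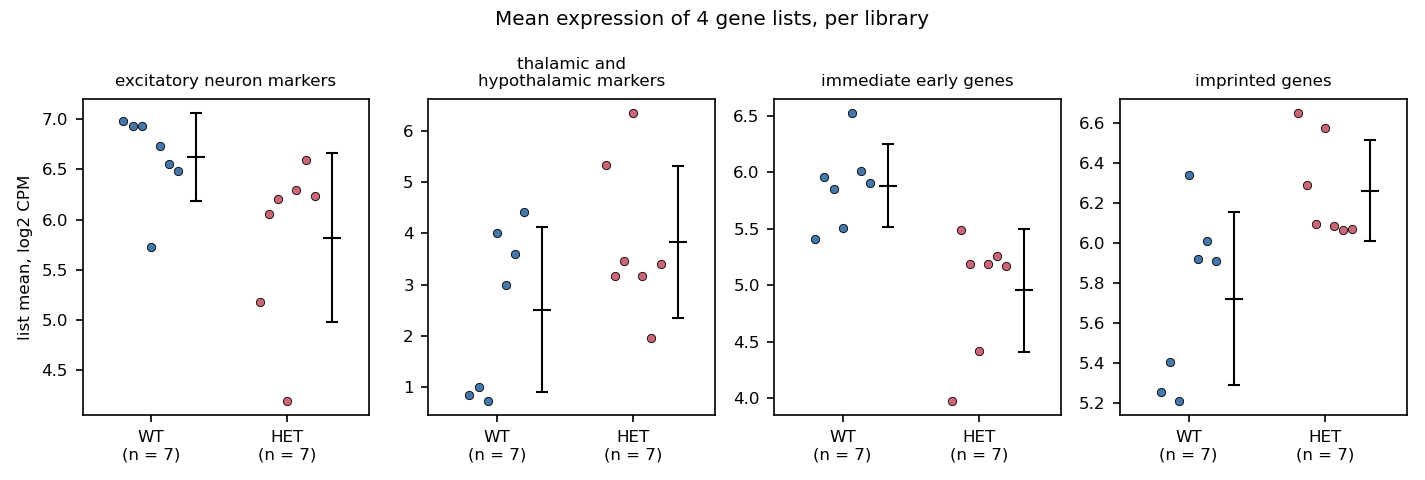
Mean log2 CPM (linear axis on the log2 scale) of excitatory neuron markers, thalamic and hypothalamic markers, immediate early genes and imprinted genes, 1 point per library, blue for WT and red for HET, with the mean and SD beside the points (n = 7 each). HET 4 at 4.19 and HET 1 at 5.17 were lowest for excitatory markers, and the same libraries were highest for thalamic markers.

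Over the 38 lists tested by camera with an estimated correlation 0 changed, with 2 at unadjusted p under 0.05, the immediate early and the imprinted genes, and a lowest adjusted p of 0.677. Fry called the same 2 lists and had 9 at unadjusted p under 0.05, and camera with a preset correlation called 14, none of which held with an estimated correlation. Among synaptic lists, 0 of 37 excitatory synapse genes changed in edgeR with 22 at unadjusted p under 0.05 (median log2 fold change -0.32), 0 of 29 presynaptic genes with 15 (median -0.20), and 0 of 22 inhibitory synapse genes with 1 (median -0.04). With the 3 tissue marker means as covariates these medians were -0.07, -0.03 and 0.03, and with the excitatory mean alone -0.05, -0.05 and 0.03. In these 3 lists 0 changed adjusted over the list alone. DESeq2 called 1 excitatory synapse gene higher and 5 lower, 2 presynaptic genes lower and 1 inhibitory synapse gene higher, and limma-voom called 1 higher and 9 lower, 2 higher and 7 lower, and 1 higher. The preset correlation called excitatory synapse, presynaptic and excitatory marker lists lower (adjusted p 3.07e-05, 0.00105 and 0.000431), against adjusted p = 0.677, 0.888 and 0.677 with an estimated correlation. The two-sided exact permutation p of the list mean was 0.0274 for excitatory synapse, 0.0874 for presynaptic and 0.939 for inhibitory synapse genes. After adjustment over 40 lists these were 0.117, 0.250 and 0.939. Gad1, the GABA-synthesising enzyme, stood at 468.9 ± 97.5 CPM in HET and 423.6 ± 84.5 CPM in WT.

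No cell type or region list had a gene that passed over all genes in edgeR. The counts at unadjusted p under 0.05 were 6 of 18 for excitatory neurons, 7 of 19 for inhibitory neurons, 6 of 16 for astrocytes, 0 of 18 for oligodendrocytes, 2 of 11 for oligodendrocyte precursors, 7 of 16 for microglia, 1 of 18 for endothelial and mural cells and 0 of 17 for meningeal fibroblasts. They were 2 of 15 for choroid plexus, 2 of 11 for ependyma, 0 of 18 for striatal neurons, 5 of 19 for thalamus and hypothalamus, 3 of 10 for olfactory bulb, 2 of 13 for hippocampus and 5 of 8 for blood. Adjusted over the list alone, 5 microglial genes fell, 1 inhibitory marker rose and 3 fell, and 1 precursor, 2 hippocampal and 4 blood markers fell, while the excitatory, astrocyte, oligodendrocyte, endothelial, meningeal, choroid, ependymal, striatal, thalamic and olfactory lists had 0. DESeq2 called 1 excitatory marker lower, 1 inhibitory marker higher and 2 lower, 1 astrocyte marker higher, 1 precursor and 2 microglial markers lower, 2 thalamic markers and 1 olfactory marker higher, 2 hippocampal and 2 blood markers lower, and 0 in the others. Limma-voom called 3 excitatory markers lower, 1 inhibitory marker higher and 5 lower, 3 astrocyte markers higher, 1 precursor and 2 microglial markers lower, 1 choroid and 1 olfactory marker higher, 1 hippocampal marker lower, and 0 in the others. The preset correlation also called microglial markers lower (adjusted p 2.68e-05) and ependymal and thalamic markers higher (0.0191 and 0.00125), against adjusted p = 0.677, 0.888 and 0.888 with an estimated correlation. Microglial list means differed by -0.25 log2 CPM (two-sided exact permutation p = 0.0175) and olfactory bulb means by 1.11 (p = 0.0332), both 0.117 after adjustment over 40 lists. The microglial median was -0.21, and -0.20 with the 3 tissue marker means. Apart from these and the excitatory list, exact permutation p for cell type and region lists lay between 0.128 and 0.857.

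The most abundant marker of each remaining type or region showed no call in edgeR with all libraries. The microglial receptor gene Csf1r had 91.0 ± 11.1 CPM in HET and 105.1 ± 6.35 CPM in WT (log2 fold change -0.21, adjusted p 0.123 in edgeR), and the precursor marker Cspg5 268.5 ± 32.8 and 330.7 ± 31.0 CPM (-0.30, adjusted p 0.0787). Log2 fold changes were -0.33 for the astrocyte transporter gene Slc1a2, 0.13 for the myelin gene Mbp, 0.07 for the pericyte marker Rgs5, 0.21 for Ptgds of the meninges, -0.29 for Enpp2 of choroid plexus, 0.40 for Foxj1 of ciliated cells, 0.28 for striatal Adcy5, 0.41 for Cdhr1 of olfactory bulb, -0.11 for hippocampal Wfs1 and -0.67 for the haemoglobin gene Hbb-bs. Their adjusted p in edgeR lay between 0.138 and 0.818. DESeq2 called Cspg5 and Hbb-bs lower (adjusted p 0.0217 and 0.0481), limma-voom called Cspg5 (0.0172), and edgeR called it without HET 6 (0.0359) or without WT 4 (0.0336). Striatal markers varied within each genotype, from 3.86 to 7.27 log2 CPM in HET and from 3.501 to 6.89 in WT.

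Among the metabolic and stress lists, 2 of 74 nuclear genes of oxidative phosphorylation fell and 72 did not pass. Both encode subunits of respiratory complex III: Uqcrq (104.2 ± 5.71 to 90.3 ± 2.80 CPM, log2 fold change -0.21, adjusted p 0.0461) and Uqcr11 (70.8 ± 6.86 to 57.2 ± 4.45 CPM, -0.31, adjusted p 0.0472 in edgeR). Their calls held in 2 and 3 of the 14 fits with a library left out, ending for both without HET 1, 2, 3, 4 or 7 or without any WT library other than WT 4, and for Uqcrq without HET 5, where the highest adjusted p was 0.0983 and 0.104. The block, the Y-linked covariate and the 3 tissue marker means (adjusted p 0.0761 and 0.152) ended both as well, with log2 fold changes of -0.21, -0.26 and -0.24 for Uqcrq and -0.30, -0.23 and -0.27 for Uqcr11. The list had 0 rises and 11 falls adjusted over the list alone, 10 lower in DESeq2, 9 lower in limma-voom and 21 at unadjusted p under 0.05. Its median was -0.08, -0.11 with the 3 tissue marker means and -0.13 with the excitatory mean. The 12 tested mitochondrially encoded genes had 0 at unadjusted p under 0.05 and 0 calls by edgeR, DESeq2 or limma-voom, or adjusted over the list alone. Heat shock and unfolded protein genes had 0 calls of 28 in edgeR, 9 at unadjusted p under 0.05, 4 lower in DESeq2, 8 lower in limma-voom and 4 that fell adjusted over the list alone. The 25 autophagy genes had 0, 9, 4 lower, 4 lower and 3 that fell in that order, and the 16 glucocorticoid response genes 0, 3, 1 lower, 2 lower and 1 that fell. The heat shock median was -0.16, -0.27 with the 3 tissue marker means and -0.30 with the excitatory mean, where the unadjusted camera p went from 0.143 to 0.0340 and 0.0163 and 0 lists passed after adjustment. With the excitatory mean the unadjusted fry p went from 0.0325 to 0.00202 for heat shock genes. For oxidative phosphorylation genes it went from 0.0445 to 0.0126. The 77 cytosolic ribosomal protein genes had 0 in edgeR, 6 at unadjusted p under 0.05, 1 lower in DESeq2, 5 lower in limma-voom and 0 adjusted over the list alone. The 24 interferon response genes all had positive log2 fold changes (median 0.28) with 0 calls in edgeR, 4 at unadjusted p under 0.05, 1 higher in DESeq2, 0 in limma-voom and 0 adjusted over the list alone. Their median turned to -0.06 with the 3 tissue marker means as covariates and to -0.07 with the excitatory mean, and HET 4, the highest library in thalamic markers, had the highest interferon mean (2.73 log2 CPM). The 22 complement and antigen presentation genes had 0 in edgeR, 7 at unadjusted p under 0.05, 1 higher in DESeq2, 1 higher in limma-voom and 0 adjusted over the list alone. The preset correlation called oxidative phosphorylation, heat shock and autophagy lists lower (adjusted p 2.63e-07, 3.07e-05 and 0.00859) and interferon genes higher (0.0164), against adjusted p = 0.888, 0.677, 0.677 and 0.888 with an estimated correlation. The two-sided exact permutation p of the list mean was 0.0321, 0.0187, 0.00932 and 0.171 in that order. After adjustment over 40 lists the first 3 were 0.117 and that of interferon genes 0.341.

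The ATAC-seq comparison asked how far open chromatin of HET and WT cortex coincided. The HET list held 30862 peaks over 14.62 Mb (median width 423 bp) and the WT list 19272 peaks over 10.41 Mb (median 490 bp), 1.6 times as many in HET. Of the WT peaks 17180 overlapped a HET peak by at least 1 bp, or 89.1% (exact binomial 95% interval 88.7% to 89.6%). Of the HET peaks 17244 overlapped a WT peak, or 55.9% (55.3% to 56.4%). Moving the WT peaks by 100 kb left 395 overlaps (2.05%). The 13618 peaks seen in HET alone were narrower than the shared HET peaks (median 285 against 577 bp), as were the 2092 seen in WT alone (329 against 521 bp). Promoters, within 1 kb of a transcription start, held 52.7% of shared HET peaks, 14.4% of HET-only peaks (13.8% to 15.0%) and 20.2% of WT-only peaks (18.5% to 22.0%). Introns held 20.1%, 42.1% and 35.9%, and intergenic sequence 18.4%, 35.3% and 35.3%. Each genotype had 1 list, by its name from merged libraries, so no replicate spread was available, and the intervals cover counting error only.

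**Figure D4:**
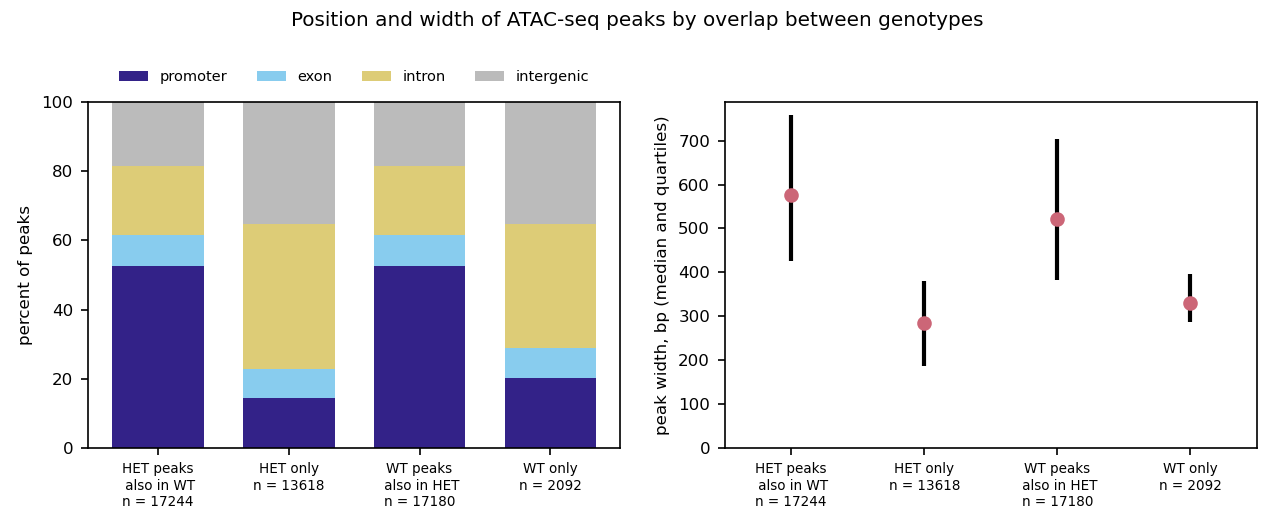
Left, percent of peaks (linear axis from 0 to 100) in promoters, exons, introns and intergenic sequence; right, peak width in bp as median (point) and quartiles (line), for HET peaks also in WT, HET-only, WT peaks also in HET and WT-only peaks. Promoters held 52.7% of shared HET peaks and 14.4% of HET-only peaks, whose median widths were 577 and 285 bp.

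At Adnp itself both lists had a peak over the transcription start on mm10 chromosome 2, at 168206967 to 168207628 in HET and 168206974 to 168207603 in WT. A second peak inside the gene lay at 168206230 to 168206383 in HET and another at 168205267 to 168205603 in WT. Of the 10 rising genes named by size, Prss41 had a promoter peak in HET alone (chromosome 17, 23843864 to 23844206, 343 bp) and 9 had none in either list, among them Sycp2, Prss50, Rnf17 and Best1. Of the 10 falling genes, Dusp6, Pantr1 and Panct2 had promoter peaks in both lists, Eya4 in HET alone (chromosome 10, 23349483 to 23349787) and 6 had none. The promoter peak of Dusp6 lay at chromosome 10, 99262958 to 99263631 in HET and 99262955 to 99263638 in WT. The widest HET-only promoter peaks were at Ptk2b (chromosome 14, 66279159 to 66281113, 1955 bp), Rab6b (chromosome 9, 103111494 to 103112929), Tceal9 (chromosome X, 136244798 to 136245974), Dgkd (chromosome 1, 87852999 to 87854163) and Gabrg1 (chromosome 5, 70842202 to 70843306). The widest WT-only promoter peaks were at Plpp6 (chromosome 19, 28963111 to 28964158, 1048 bp), Reep2 (chromosome 18, 34840719 to 34841645), Sdc1 (chromosome 12, 8771075 to 8771923), Mid2 (chromosome X, 140664539 to 140665373) and Gas1 beside Gm48488 (chromosome 13, 60175994 to 60176777). None of these 11 genes passed in edgeR, with adjusted p from 0.0525 for Mid2 to 0.803 for Gm48488.

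The last comparison asked whether genes with a promoter peak in a single genotype also differed in RNA. Of 18050 genes, 10043 had a promoter peak in both lists (37 rose, 46 fell), 1459 in HET alone (17 rose, 5 fell), 293 in WT alone (0 changed) and 6255 in neither (52 rose, 18 fell). The median log2 fold change was 0.09 for genes with no promoter peak, 0.03 for HET-only genes, 0.01 for WT-only genes and -0.01 for genes with both, so a positive median did not go with HET-only peaks alone. Between HET-only genes and genes with both the difference was 0.032 with a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give (2e-05 after adjustment over 2 comparisons). For WT-only genes the difference was 0.021 (permutation p = 0.0717), and 0.052 (permutation p = 5e-05) with promoters taken as 5 kb either side of the start. The HET-only genes were lower in expression than genes with both (median 3.75 against 4.90 log2 CPM), and genes with no peak stood at 1.18. With fold changes centred against genes of similar mean expression the difference was 0.015 (permutation p = 0.00686), and with the 3 tissue marker means as covariates 0.014 (permutation p = 0.00387). Genes are not independent replicates, so these p-values describe the lists and not the spread between mice.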

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

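Of the tests in this part, the tissue composition test was written before its result was seen, and the test of a genotype effect on cortical neurons and the comparison with other splits were chosen only after it. Among 182 checks of a library against the other 6 of its group, 12 stood apart by Dixon's criterion, and chance alone gives about 1 in 20.

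WT replicate 4 accounted for 6 of the 12. Its mitochondrial share was 5.64%, with the next WT library at 5.09%. Its Rec8 level was 12.6 CPM against 6.47 CPM in the next WT library, and its Wfs1 level 267.2 CPM against 167.7 CPM. Its mean of excitatory synapse genes was 7.18 log2 CPM (next 7.54), of presynaptic genes 8.10 (next 8.498) and of excitatory neuron markers 5.73 (next 6.48).

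The other 6 were HET libraries. HET 5 stood at 66.7 CPM for Uqcr11, with the next HET library at 59.0 CPM. HET 6 was lowest for oligodendrocyte and myelin markers (5.73 log2 CPM, next 7.04), oligodendrocyte precursor markers (4.58, next 5.05) and olfactory bulb markers (0.70, next 1.64). HET 4 was lowest for meningeal fibroblast markers (2.70 log2 CPM, next 3.47), and HET 7 was highest for hippocampal markers (3.75, next 2.97).

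The pattern weighed here is the lower level of cortical excitatory markers and the higher level of thalamic markers in HET. HET 4 and HET 1 show it most. Among the WT libraries WT 4 was lowest in excitatory markers (5.73), while WT 7 was highest in thalamic markers (4.42, with WT 4 at 4.00). WT 7, WT 4 and WT 6 lay above HET 2, 3, 5, 6 and 7 in thalamic markers, so that part of the pattern was not shared by all HET libraries. A difference in how much subcortical tissue each dissection held could give this pattern. Across all 18050 genes the HET against WT fold change correlated at r = -0.616 with the slope of each gene on the excitatory marker mean within the WT libraries alone, where genotype cannot act (genes are not independent replicates). This r passed the limit set beforehand as the sign of tissue composition. That size does not stand out: with fold changes as differences of mean log2 CPM r was -0.674, and 225 of the 3432 splits of the 14 libraries gave a value as far from 0 (6.6%). Among the 108 splits with an excitatory difference as large as the real one, the median size of r was 0.662. An r of this size thus goes with an imbalance in these markers and does not tell its origin. A genotype effect on cortical neurons stays open as well. With thalamic and striatal marker means as covariates the excitatory difference went from -0.80 to -0.30 log2 CPM (95% interval -0.75 to 0.16), and on the linear scale from -38.4 to -20.3 CPM (-39.4 to -1.1), so the scales part on whether a difference remains. The explanations cannot be told apart, as r does not tell the origin of the imbalance and the interval on the log2 scale holds 0.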

How the results depend on the processing

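Chosen only after seeing the data were the fits with marker means as covariates, the fits without 2 or 5 libraries, the equal-number and 300 bp peak sets, the promoter test centred by expression, and the beta-catenin mean without 2 genes. No named gene with a call turned direction in any alternative. Values without a call did: the Adnp fold change with limma-voom (-0.06) and, in at least 1 alternative each, those of Eif2s3y, Uty, Gad1, Slc1a2, Mbp, Ptgds, Foxj1 and Wfs1, with Mbp going from 0.13 to -0.28 with the excitatory and -0.21 with the 3 tissue covariates. List medians turned with the excitatory or the 3 tissue covariates for thalamic (1.19 to -0.34 and 0.02, itself a covariate in the latter, which holds it near 0) and excitatory markers (-0.65 to 0.00 and -0.01, itself a covariate in both), for oligodendrocyte (0.15 to -0.28 and -0.22), choroid plexus (-0.10 to 0.05 and 0.43) and interferon genes (0.28 to -0.07 and -0.06), and for ChAHP, BAF, inhibitory synapse, inhibitory neuron, astrocyte, endothelial and complement genes. The beta-catenin mean difference of 0.10 became 0.019 without Tcf7l2 and Lef1. The count of 175 changed genes became 1403 with DESeq2, 106 with no filter (35384 genes tested), 10 with a replicate block, 1886 with limma-voom, 4 with Y-linked expression as a covariate, 24 with 1 surrogate variable, 13 with the excitatory list, 27 with 3 tissue lists, 13 without the 2 libraries lowest in excitatory markers, 5 without the 5 end libraries (both with fewer samples) and 1195 at adjusted p under 0.1, and it ran from 11 to 1672 with 1 library left out; for the covariates and tools the cause was not tested. It was 181 with DESeq2 size factors and 210 with the stricter filter. The Y-linked covariate overlaps with genotype, as given above, so its count of 4 cannot be read apart from that overlap. Replicate numbers did not pair the samples: same-numbered residuals correlated between -0.28 and 0.33, and 1 of 7 HET and 0 of 7 WT libraries matched best with their own number, so the block result counts calls only. Gene lists stayed at 0 except for 14 with the preset correlation and 2 with fry, and at 0 with each library left out. The Adnp log2 fold change did not pass in any of 26 alternatives (-0.06 to 0.23, and 0.01 to 0.13 with 1 library left out). The WT peaks overlapping HET were 78.5% at 50% reciprocal overlap, 76.9% with the widest HET peaks in equal number, 85.6% at 300 bp or more and 89.2% on autosomes and X. The HET-only promoter difference held from 0.014 to 0.041, and the WT-only one passed only at 5 kb (0.052). Alternatives that need peak q values (a stricter q, or equal numbers by q) were not run. In the simulated data, with genes drawn separately, 29 of 50 genes changed 2-fold were recovered at this depth and number of libraries.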

Other observations

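All tests of the germline and ATAC-seq patterns in this part were chosen only after the result was seen, except the test for germ cell RNA and the counts of other splits, which were written before. Genes named here outside the naming rule were chosen after their values were seen.

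The largest fold change among the 11 genes called with every library left out belonged to E230025N22Rik (chromosome 18, 36684923 to 36695925), which rose 31.1-fold from 0.158 ± 0.0910 to 5.01 ± 1.81 CPM (SD, n = 7 each; adjusted p 4.71e-05 in edgeR). Plcg2, a phospholipase C of immune receptor signalling, rose 1.84-fold from 4.68 ± 0.720 to 8.61 ± 0.816 CPM (adjusted p 0.00159 in edgeR). Sec24d, a coat protein of vesicles leaving the endoplasmic reticulum, rose 1.64-fold from 16.0 ± 2.63 to 26.2 ± 2.08 CPM (adjusted p 0.00364 in edgeR). The predicted gene Gm15707 had a log2 fold change of 2.07, from 0.163 to 0.695 CPM. With 3 tissue marker means as covariates all 4 kept an adjusted p under 0.05 in edgeR (2.85e-05 for E230025N22Rik, 0.0268 for Plcg2, 0.00538 for Sec24d and 0.0268 for Gm15707). Of 12 alternatives other than leaving out a single library, E230025N22Rik was called in 12, Sec24d in 10, Plcg2 in 9 and Gm15707 in 8 of the 11 that tested it, since the stricter filter removed it. The Y-linked covariate and the fit without 5 end libraries ended the calls of the last 3, and the replicate block those of Plcg2 (adjusted p 0.0526) and Gm15707 (0.0610). Each was higher in all 7 HET libraries than in any WT library.

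Several of the genes that rose belong to germ cells. From 73 genes of meiosis, piRNA silencing and related germline functions, listed after Sycp2 and others were seen to rise, 39 were tested, 8 rose and 0 fell: Sycp2, Prss50, Rnf17, Xlr3a, Rec8, Syce1, Gpat2 and Tdrd9. Only Sycp2, Prss50 and Rnf17 of these were called with every library left out. A replicate block ended the calls of Xlr3a, Rec8, Syce1, Gpat2 and Tdrd9 (adjusted p 0.0610 to 0.0962 in edgeR). Syce1, another synaptonemal complex gene, went from 0.0814 to 0.685 CPM, and Gpat2 and Tdrd9, both of the piRNA pathway, from 0.331 to 0.982 and from 0.468 to 1.03 CPM. The 31 genes that were not called also lay higher, with 23 positive, 12 higher and 1 lower at unadjusted p under 0.05, and a fry p of 0.00148 (0.0187 with the tissue covariates). Camera with an estimated correlation gave p = 0.0313 for them, and p = 0.0661, no longer under 0.05, with the tissue covariates. Neither test matched genes by expression. The median log2 fold change of the 31 was 0.22. It was 0.09 over the 6255 genes with no promoter peak, whose expression was low (median 1.18 log2 CPM), so part of the shift need not be particular to germline genes. Prdm9, a meiotic histone methyltransferase on the list, stood at 2.11 ± 0.551 CPM in HET and 1.46 ± 0.408 CPM in WT and did not pass (adjusted p 0.160 in edgeR).

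A lost repression of germline genes in Adnp HET cortex is a hypothesis that these values are consistent with, and it was found and tested on the same data. Striatal or thalamic tissue in the dissection is argued against as the whole source of the rise of the 8 called genes. With the 3 tissue covariates their median log2 fold change was 1.91 against 2.04 without (the median of the single genes' SE was 0.28 and 0.29), the lowest was 1.11, and each of the 8 lay above 0 by more than 2 of its own SE. It was 1.87 (lowest 1.05) with the excitatory covariate and 1.76 (lowest 0.89) without the 5 end libraries. Calls remained for 5, 3 and 3 of the 8 in that order, while all 8 kept an unadjusted p under 0.05 in each. With the 3 tissue covariates the calls of Syce1 (log2 fold change 3.00, SE 0.53, to 2.60, SE 0.57), Gpat2 (1.55, SE 0.32, to 1.11, SE 0.33) and Tdrd9 (1.134, SE 0.25, to 1.123, SE 0.32) ended, where the fold fell or its SE grew and fewer genes passed over all genes (27 against 175). Olfactory bulb markers, at 1.70 log2 CPM in HET and 0.59 in WT, were not among the covariates, so other tissue of this kind was not addressed. RNA of haploid germ cells in the libraries is argued against, since their genes Prm1, Prm2, Tnp1 and Tnp2 together reached 0.402 CPM in HET. That is far under the excess of 4.13 CPM of Sycp2 alone and 27.9 CPM over the 8 genes. RNA of germ cells at earlier stages, which these markers do not cover, was not tested for. A variant carried along near Adnp stays open for single genes such as Sycp2, which lies within 20 Mb of Adnp on chromosome 2. In that window 3 of 390 tested genes were called, against 175 of 18050 among all tested genes. Such a share does not speak to a variant at a single gene. Sycp2, Prss50, Rnf17, Xlr3a and Rec8 had no promoter peak in either ATAC-seq list, and protein, DNA methylation and histone marks at these genes were not analysed here.

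The larger number of ATAC-seq peaks in HET may follow depth or calling power and not chromatin. Of the WT peaks 89.1% overlapped a HET peak, and 76.9% overlapped the widest HET peaks in equal number, so part of that overlap went with the length of the HET list. Peaks of 1 list alone were narrower than shared peaks in both genotypes (median 285 against 577 bp in HET, 329 against 521 bp in WT), with 14.4% against 52.7% in promoters in HET and 20.2% against 52.5% in WT, so these traits do not separate the explanations. Depth and a genotype effect on open chromatin both stay open, as each genotype had 1 list of unknown depth.

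Of 100 splits of the 14 RNA libraries into 7 and 7, the real split included, 3 gave at least 175 changed genes. This is under the limit of 5 in 100 set beforehand, so a random division of the libraries seldom gave such a count. It is not excluded as the source, since 1 split other than the real one gave 553 genes and another gave more. The highest other split gave 1613 genes and the median of the others was 0. That split set HET 1, 2, 3, 4 and 7 with WT 4 and WT 6 against the rest, and a count several times the real value points to a structure of the samples. For gene lists the real value was 0, which each of the 100 splits reaches (100 of 100, highest other 1), so that count says nothing about chance.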
